A study of Homo sapiens with 28 samples.

How the data were processed

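RNA abundance was measured in 28 libraries of HEK293T cells, an established human embryonic kidney line. Per the labels, knockdown was by CRISPR interference, in which a catalytically inactive Cas9 bound near a gene's start represses its transcription. Control cells carried a non-targeting guide, and the other lines carried guides against DELE1, HRI (gene symbol EIF2AK1) or OMA1. Each of these 4 lines was left untreated or given 1.25 ng/mL oligomycin, an inhibitor of the mitochondrial ATP synthase, for 16 hours. That made 8 groups of 3 libraries. A separate set of 4 libraries held wild-type cells with and without 50 ug/mL doxycycline, an antibiotic that also blocks mitochondrial translation, 2 libraries in each group. The length of the doxycycline treatment is not given in the sources used here. Per the labels, polyadenylated RNA was extracted with a column kit and made into 3' tag libraries, which sample the end of each transcript, so a value does not scale with transcript length.

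The authors deposited one table of normalized values for the knockdown lines and another for doxycycline. Salmon 0.14.1, DESeq2 1.20.0 and genome build GRCh38 are named by the submitters' processing notes; the annotation release, any filter and the way transcripts were summed to genes are not given in the sources used here. The deposited unit is a normalized signal: in each library, the authors divided the gene counts by one size factor. This was tested on the values, and 100% of them came out as whole reads within a tolerance of 0.1 reads once the step of each column was taken as the inverse of its size factor. The test is weaker for control oligomycin replicate 2, whose size factor of 1.0028 is near 1. With no step taken, 61.1% of its values were within that tolerance of a whole number, against 23.3 to 37.1% in the other 23 libraries of the knockdown table. Among its values of at least 50 the share was 5.2%. Values are comparable between libraries of one table and not between the tables, so the tables were never fitted together. Recovered depth was 1297821 to 2047516 reads per library in the knockdown table and 1263596 to 2882704 in the doxycycline table. No molecular identifiers were used here, so the intervals and floors below cover counting error only. There were 15225 genes listed for the knockdown lines and 12464 for doxycycline, by identifier and symbol. Of these, 564 and 341 identifiers lay outside the primary assembly, and 264 and 134 symbols stood on more than one identifier. Reads of such a gene may be divided between near-identical copies, so the level of a single copy is uncertain. DELE1 appears in the tables under its older symbol KIAA0141. Among the symbols for the knockdown lines, 24 read as dates and were not named here. Gene positions were taken from a GENCODE annotation of GRCh38.

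Tests were run on log2(value + 1), which understates the fold changes of genes with few reads. Genes with a value of at least 10 in at least 3 libraries (10830 genes) or, for doxycycline, in at least 2 libraries (10007 genes) were tested. limma 3.58.1 in R 4.3.3 was used (lmFit, contrasts.fit and eBayes with a trend), with 1 fit of 8 group means for the knockdown table and its own fit for doxycycline. All tests were two-sided. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The comparisons were the oligomycin response in each line, the difference between each knockdown line's response and the control response, each untreated knockdown line against untreated control, a limma F test of differences among the 3 knockdown responses, and the doxycycline response. Gene lists, 21 in all, were fixed before the data were examined, as were the comparisons, the tests and most of the other settings tried. Lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. A score per library was the mean log2(value + 1) over the tested members of 4 integrated stress response lists, compared by an exact permutation test. Overlaps of called genes between drugs were tested with Fisher's exact test.

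Genes were named by a rule also fixed before the data were examined. EIF2AK1, DELE1 and OMA1 were named in every comparison. In each response, the 10 largest rises and the 10 largest falls were named among genes with adjusted p under 0.05, a mean of at least 50 in one group, a symbol, and no overlap between the libraries of the groups. In each difference of responses, the 8 largest absolute differences were named, with the same threshold and mean. For each list, up to 4 members with the largest absolute moderated t statistic could be named. Any other gene is said to have been chosen after its values were seen.

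Counts of called genes and named genes were recomputed with a pseudocount of 0.5 or 5, no filter or a filter at 50, scaling to equal library totals, quantile normalization, a replicate block and fits of only the groups compared (both for the knockdown table), leaving out each library, and counts of recovered reads in edgeR 4.0.16 and DESeq2 1.42.0. List tests were repeated with an estimated correlation, fry, quantile normalization and the block. ISR score changes with oligomycin were repeated with a pseudocount of 5, both scalings, the block and each library left out, and the overlap between drugs with a fold change of at least 1.5 in both. After the data were seen, 3 more settings were added: leaving out the pair of libraries that stand apart, summing values per gene symbol, and for doxycycline a block on the number in the column names. On the control response, limma called 378 genes, edgeR 377 and DESeq2 363. The pipeline was tested on simulated data with the depth of these libraries. In the control comparison, 14.9% of genes with a 1.5-fold change were recovered, 55.2% with a 2-fold change and 89.4% with a 4-fold change, with 6 false calls in 10723 genes. For a difference between responses, the shares were 4.5%, 31.3% and 74.2%. For doxycycline, 0% of 1.5-fold, 20.9% of 2-fold and 80.3% of 4-fold changes were recovered, with 12 false calls by limma, 23 by edgeR and 11 by DESeq2. Figures were drawn with matplotlib 3.10.9. All deposited columns were used, and none was left out. Markers of other cell types were given as values only. A few genes of the preset lists and of the naming rule are not reported here.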

Results

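The data were 3' tag RNA counts from HEK293T cells, taken to ask how a mitochondrial fault reaches the integrated stress response (ISR), a program in which kinases such as HRI phosphorylate eIF2 alpha and raise translation of ATF4. The series title names OMA1, a protease of the inner mitochondrial membrane, DELE1, a mitochondrial protein, and HRI, encoded by EIF2AK1, as a relay for this signal. The knockdown set held 24 libraries in 8 groups of 3, namely control, DELE1, HRI and OMA1 knockdown cells without and with oligomycin. Depth ran from 1297821 to 2047516 reads per library. The doxycycline set held 4 libraries of wild-type cells. The untreated ones had 1263596 and 1518221 reads, and the treated ones had 2429941 and 2882704. Values are mean ± SD with n = 3 for the knockdown set and n = 2 for doxycycline. All p-values measure at most the spread between these libraries, as the labels do not say if these are separate cultures. Among the knockdown set, 2 libraries stood apart. On the first principal component, which held 12.11% of the variance, DELE1 knockdown untreated replicate 3 lay at 82.6 and HRI knockdown untreated replicate 2 at 37.78, against -12.143 to 10.33 for the other 22. Their root mean square deviations from the group mean were 0.597 and 0.505 on the log2 scale, against 0.408 to 0.497 in the others.

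The first question was how far each guide lowered its target. In untreated cells DELE1 (ENSG00000081791, chromosome 5, 141923808 to 141942047) fell from 42.1 ± 7.41 in control to 0.880 ± 1.52 in its knockdown line, which was 2 reads against 127, or 1.81% of control (exact 95% interval 0.217 to 6.68%). EIF2AK1 (ENSG00000086232, chromosome 7, 6022244 to 6059230), which overlaps AIMP2 on the other strand, fell from 197 ± 17.2 to 10.1 ± 3.44, or 4.95% of control (3.29 to 7.18%). OMA1 (ENSG00000162600, chromosome 1, 58415384 to 58546802), which overlaps DAB1 on the same strand, fell from 105 ± 15.6 to 1.49 ± 0.740, or 1.40% of control (0.378 to 3.61%). With oligomycin the remaining shares were 0.637% (0.016 to 3.60%) for DELE1, 5.77% (4.18 to 7.79%) for EIF2AK1 and 1.94% (0.623 to 4.59%) for OMA1. In the lines not aimed at them, these genes stood at 79.5% to 134% of control. By limma the untreated changes were -4.79 for DELE1, -4.21 for EIF2AK1 and -5.45 for OMA1 on the log2 scale, with adjusted p of 1.29e-07, 6.68e-11 and 3.13e-09. The DELE1 call was lost when only the 2 groups compared were fitted (adjusted p 0.123).

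**Figure D1:**
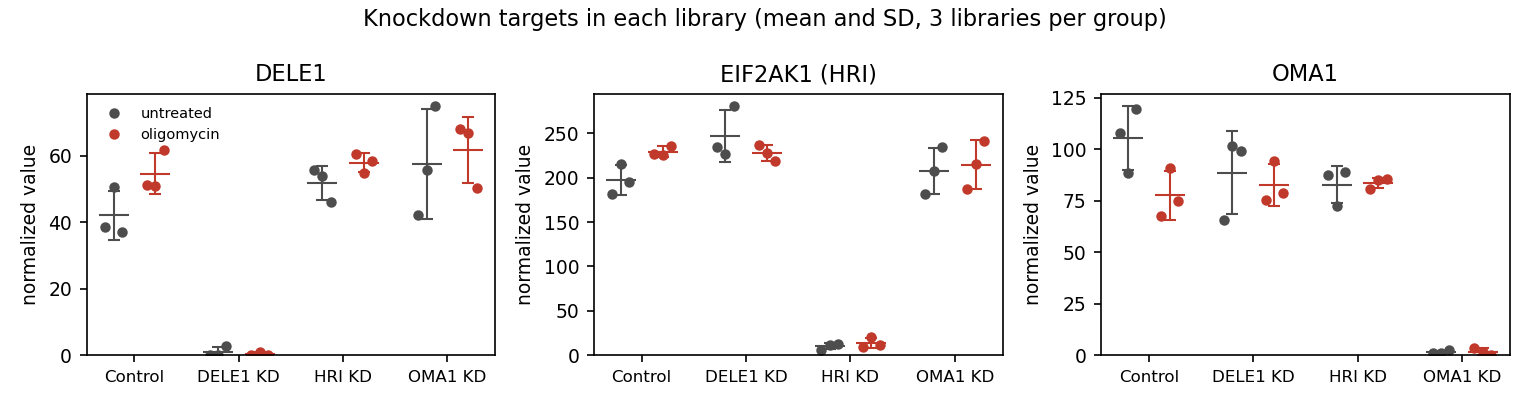
Normalized values (y axis, reads divided by the library's size factor) of DELE1, EIF2AK1 (HRI) and OMA1 in the 4 lines (x axis), with points for libraries, bars for mean and SD, grey for untreated and red for oligomycin. Each gene was near 0 only in its own knockdown line, for example DELE1 at 0.880 against 42.1 in untreated control.

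The next comparison asked what each knockdown did without stress. Untreated DELE1 knockdown cells had less SLC7A11, the cystine transporter, at 66.7 ± 20.2 against 142 ± 22.7 in control (log2 change -1.11, adjusted p 0.00534). A copy of the ribosomal protein gene RPS18 (ENSG00000235650), uncertain because it has near-identical copies, stood at 1003 ± 126 against 1857 ± 145 (adjusted p 0.00534). DDIT4, a stress-induced inhibitor of mTORC1, was lower in HRI knockdown cells, at 34.4 ± 9.24 against 103 ± 2.72 (-1.59, adjusted p 0.000431), and in OMA1 knockdown cells, at 40.7 ± 4.54 (adjusted p 0.00727). JUN, an AP-1 transcription factor, was also lower in both, at 341 ± 16.5 in HRI and 343 ± 21.8 in OMA1 knockdown cells against 552 ± 14.1, with adjusted p of 9.21e-06 and 1.04e-05. Besides the targets, SLC35A5 was lower in DELE1 knockdown cells (7.69 ± 5.59 against 34.5 ± 1.36, adjusted p 0.0264) and B9D1 higher in OMA1 knockdown cells (29.1 ± 6.90 against 8.11 ± 3.94, adjusted p 0.00877); both were chosen after their values were seen.

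In all, limma called 4 genes in untreated DELE1, 3 in HRI and 4 in OMA1 knockdown cells, targets included, of 1813, 626 and 637 at unadjusted p under 0.05. DESeq2 called 37, 11 and 9. Fitting only the groups compared gave 2, 7 and 8 calls and ended those of SLC7A11 (0.635), the RPS18 copy (0.253) and DDIT4 in HRI knockdown cells (0.0875). The DELE1 count rose to 693 without DELE1 knockdown untreated replicate 1, 11 without replicate 2 and 7 without HRI knockdown untreated replicate 2, and fell to 2 without control untreated replicate 1 and 1 without replicate 3. The HRI count was 8 without DELE1 knockdown untreated replicate 3. The OMA1 count was 2 without control untreated replicate 3 or OMA1 knockdown untreated replicate 1. Without control untreated replicate 3, SLC7A11 and the RPS18 copy were at adjusted p 0.0732, and DDIT4 in OMA1 knockdown cells at 0.0589. The RPS18 copy was at 0.079 without control untreated replicate 1, and DDIT4 in OMA1 knockdown cells at 0.0734 without OMA1 knockdown untreated replicate 1. Leaving out both libraries that stand apart gave 5, 6 and 7 calls.

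Among the lists, cytosolic heat shock genes were lower in untreated OMA1 knockdown cells (median log2 change -0.24, camera adjusted p 1.94e-07, 0.00172 with an estimated correlation), with 0 of 12 members called over all genes and 4 adjusted over the list alone. They were also lower in HRI knockdown cells (-0.11, adjusted p 0.00272, 0.0638 with an estimated correlation), with 3 members lower adjusted over the list alone. Cytosolic tRNA synthetases were lower in HRI (-0.12, adjusted p 0.022, 0.379 with an estimated correlation) and OMA1 knockdown cells (-0.15, adjusted p 0.00197, 0.195 with an estimated correlation). Mitochondrially encoded mRNAs were higher in DELE1 (0.24, adjusted p 2.95e-05) and OMA1 (0.16, adjusted p 0.00215) and lower in HRI knockdown cells (-0.14, adjusted p 0.00946), but with an estimated correlation their adjusted p were 0.581, 0.511 and 0.591, and after quantile normalization 0.912, 0.33 and 0.122. The remaining lists did not pass in any untreated comparison at the preset correlation. Amino acid synthesis genes in HRI knockdown cells came nearest, at adjusted p 0.0606. They passed by fry in HRI (0.0199) and DELE1 knockdown cells (0.00281). Without the libraries that stand apart, amino acid synthesis genes were lower by camera in DELE1 (median -0.176, adjusted p 0.00264) and HRI knockdown cells (-0.049, adjusted p 0.0026), ISR regulators were lower in DELE1 knockdown cells (-0.272, adjusted p 0.0387), and ribosomal proteins were higher there (0.069, adjusted p 0.000554). Ribosomal proteins in HRI knockdown cells passed after quantile normalization (0.0172).

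Oligomycin in control cells asked what the intact pathway does when ATP synthase is inhibited. CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519), an ATF4 target that breaks down glutathione, rose from 7.59 ± 4.92 to 82.4 ± 27.7. SESN2 (ENSG00000130766, chromosome 1, 28259527 to 28282491), a stress-induced regulator of mTORC1, rose from 147 ± 14.3 to 632 ± 54.2, and ASNS (ENSG00000070669, chromosome 7, 97852118 to 97872542), which makes asparagine, rose from 113 ± 7.38 to 375 ± 30.6. The cystathionine lyase gene CTH rose from 28.8 ± 1.01 to 158 ± 14.8 and the serine transporter SLC1A4 from 12.0 ± 1.63 to 61.7 ± 4.49. Chaperones moved the other way, since HSPA1B (ENSG00000204388, chromosome 6, 31827735 to 31830255) fell from 201 ± 11 to 47.3 ± 4.64 and HSPA8 (ENSG00000109971, chromosome 11, 123057489 to 123063230) from 2864 ± 63.8 to 1287 ± 74.9. Sterol genes also fell, with INSIG1 going from 222 ± 9.18 to 97.8 ± 10.6 and NSDHL from 66.7 ± 11.5 to 30.6 ± 5.54. The knockdown targets did not pass the test here, with log2 changes of 0.38 for DELE1, 0.22 for EIF2AK1 and -0.43 for OMA1.

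The limma log2 changes were 3.37 for CHAC1 (adjusted p 0.000108), 2.10 for SESN2 (3.35e-07), 1.72 for ASNS (6.35e-06), 2.41 for CTH (2.14e-05), -2.07 for HSPA1B (3.01e-09) and -1.15 for HSPA8 (7.23e-09). The other rises that the naming rule picked were DDR2, a collagen receptor (2.95), SLC1A4 (2.28), the transcription factors ATF3 (2.00) and CEBPB (1.81), and PCK2, mitochondrial PEP carboxykinase (1.95). The other falls were a second HSPA1B copy (ENSG00000231555, -1.84), PCDH17 (-1.26), INSIG1 (-1.18), CCDC86 (-1.11), NSDHL (-1.10) and the glutamate transporter SLC1A3 (-1.03). The 4 remaining genes lost the threshold without 1 library. ALDH1L2, of mitochondrial folate metabolism, rose by 3.32 but had adjusted p of 0.0881, 0.116 and 0.0764 without control oligomycin replicates 1, 2 and 3. A CARS copy (ENSG00000278191) rose by 2.30 and reached 0.138 without untreated replicate 1, 0.085 without oligomycin replicate 2 and 0.101 without replicate 3. A CEP170 copy (ENSG00000276725) with -7.10 was at 0.0813 and 0.0951 without untreated replicates 2 and 3 and at 0.0833 and 0.0759 without oligomycin replicates 1 and 3. The sterol oxidase gene MSMO1 (-1.04) was at 0.103, 0.0622 and 0.187 without untreated replicates 1, 2 and 3 and at 0.165 and 0.171 without oligomycin replicates 1 and 2, and equal library totals also ended its call (0.062).

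By limma 378 genes passed in control cells, 174 higher and 204 lower, of 10830 tested, and 77 of them changed at least 2-fold. The count was 222 and 228 without untreated replicates 1 and 2, 225 and 206 without oligomycin replicates 1 and 2, 651 without DELE1 knockdown untreated replicate 3, and 815 without both libraries that stand apart, with all 378 shared.

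**Figure D2:**
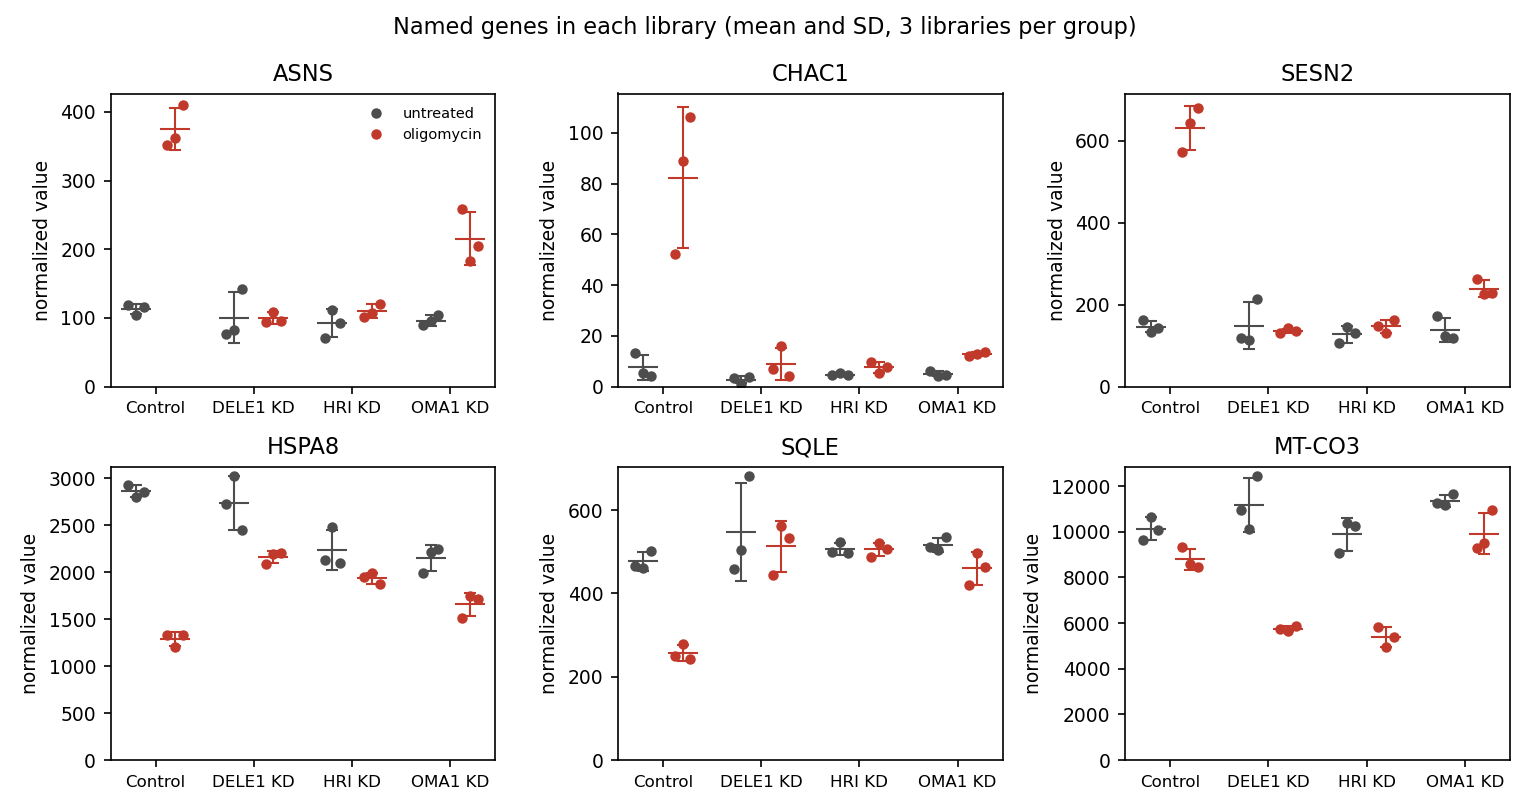
Normalized values (y axis, reads divided by the library's size factor) of ASNS, CHAC1, SESN2, HSPA8, SQLE and MT-CO3 in the 4 lines (x axis), with points for libraries, bars for mean and SD, grey for untreated and red for oligomycin. SESN2 went from 147 to 632 in control cells and HSPA8 from 2864 to 1287, with smaller steps in the knockdown lines, while MT-CO3 went from 11183 to 5752 in DELE1 knockdown cells.

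The preset lists put these genes in groups. Of 15 ISR regulators and stress genes, 10 rose and none fell (13 and 1 adjusted over the list alone), with a median log2 change of 1.61 and a camera adjusted p of 9.97e-19. The hormone gene STC2 went from 251 to 700 within it, and DDIT3, encoding CHOP, from 1.40 to 24.1. ATF4 itself, which is controlled mainly in translation, went from 768 to 1031 and did not pass (adjusted p 0.13). Amino acid synthesis genes rose in 10 of 15 (11 adjusted over the list alone; median 0.97; adjusted p 8.91e-20), among them PSAT1 from 508 to 1121 and SHMT2 from 133 to 261. Amino acid transporters rose in 7 of 10 (10 adjusted over the list alone; median 0.84; adjusted p 7.02e-16), with SLC7A11 going from 142 to 431, and tRNA synthetases in 8 of 19 (9 rose and 1 fell adjusted over the list alone; median 0.25; adjusted p 4.64e-06), with GARS from 215 to 358. Cytosolic heat shock genes fell in 10 of 12 (11 adjusted over the list alone; median -0.79; adjusted p 7.22e-25), with DNAJA1 going from 759 to 402 and HSPH1 from 1072 to 563. Cholesterol synthesis genes fell in 7 of 22 (11 adjusted over the list alone; median -0.54; adjusted p 9.13e-09), with the epoxidase SQLE going from 477 to 257. Every one of these calls held with an estimated correlation.

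Smaller shifts were found elsewhere in control cells. Mitochondrial chaperones and proteases fell in 3 of 16 (3 adjusted over the list alone; median -0.16; adjusted p 0.0188), HSPD1 going from 3059 to 2385. Glycolysis genes fell in 2 of 16 (3 adjusted over the list alone; median -0.13; adjusted p 0.00895), LDHA going from 1996 to 1406. Cell cycle genes had a median of -0.15 (adjusted p 0.0138, 0.11 after quantile normalization) with 0 members called over all genes or adjusted over the list alone. Mitochondrial ribosome genes had 2 of 78 lower (4 adjusted over the list alone; median -0.11; adjusted p 0.00413, 0.121 with an estimated correlation). Cytosolic ribosomal protein genes had 7 of 76 higher and 1 lower (9 and 1 adjusted over the list alone; median 0.08; adjusted p 2e-04, 0.214 with an estimated correlation), RPLP1 rising by 0.33. Lists that did not pass were the ER unfolded protein response (1 of 21 rose; adjusted p 0.827), nuclear OXPHOS subunits (2 rose and 1 fell of 71; 0.428, 0.0162 after quantile normalization), mitochondrially encoded mRNAs (0 of 13 called; 0.218, 0.0384 without the libraries that stand apart), p53 targets (1 of 13 rose, BBC3 from 119 to 213; 0.506) and hypoxia genes (1 of 12 rose, VEGFA from 50.2 to 148; 0.506). Immediate early genes (0 of 6 called; 0.343), replication histones (1 rose and 1 fell of 14; 0.0635, 0.0253 after quantile normalization and 0.0408 without the libraries that stand apart) and NRF2 targets (1 rose and 1 fell of 13; 0.762) did not pass either. For NRF2 targets the median (0.07) and mean (0.118) were above 0 and the test pointed down. Interferon genes and metallothioneins had under 4 tested members and were not tested as lists. Log2 changes were 0.40 for DDX58, 0.68 for IFITM2, -0.35 for MT2A and 0.29 for MT1X, and none of these was called in any response or difference.

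**Figure D3:**
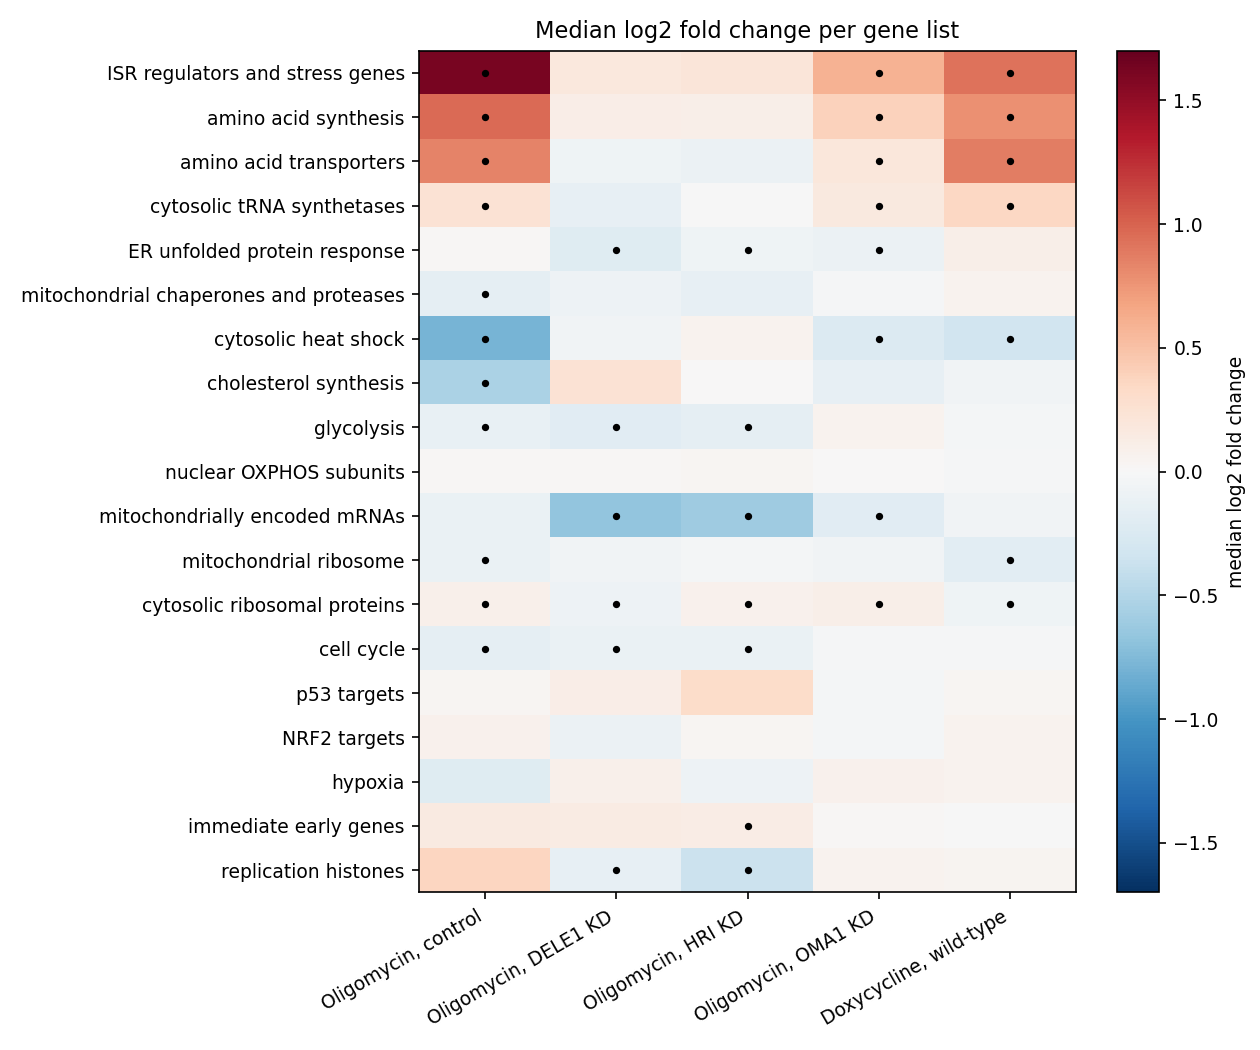
Median log2 fold change (colour) of 19 gene lists (y axis) in the oligomycin response of the 4 lines and in the doxycycline response (x axis), with black dots where camera's adjusted p was under 0.05. ISR genes had a median of 1.61 in control cells, 0.17 in DELE1, 0.20 in HRI and 0.59 in OMA1 knockdown cells; the ribosomal protein median in DELE1 knockdown cells (-0.08) turns to 0.08 with equal library totals and 0.07 with quantile normalization, and the heat shock median there (-0.06) turns to 0.10 and 0.12.

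The same drug in DELE1 knockdown cells asked what remains without DELE1. Mitochondrially encoded mRNAs, which specify core subunits of the respiratory chain, fell in 12 of 13 cases. MT-CO3 went from 11183 ± 1178 to 5752 ± 106 (log2 change -0.95, adjusted p 4.43e-07) and MT-ND3 from 19554 ± 7216 to 8570 ± 449 (-1.13, adjusted p 8.59e-05). MT-ATP8 (-1.37), MT-ND5 (-1.19), MT-ATP6 (-1.09) and the nuclear copy MTND1P23 (-1.31) were also among the largest falls. Untreated replicate 3, which stands apart, had 10.167% of its reads in these mRNAs, against 7.426% and 6.732% in replicates 1 and 2. Without it the changes were -0.873 for MT-CO3, -0.846 for MT-ND3, -1.012 for MT-ATP8, -0.867 for MT-ND5, -0.724 for MT-ATP6 and -0.915 for MTND1P23, each still called, and without both libraries that stand apart 12 of the 13 mRNAs were lower. The chaperone gene HSPA1B rose from 192 ± 28.9 to 335 ± 47.0 (0.80, adjusted p 0.00345), the kinase gene MAPK9 from 53.6 ± 14.2 to 117 ± 7.35 (1.14, adjusted p 0.00345) and JUN from 555 to 863 (0.64, adjusted p 4.1e-05). The ISR genes ASNS (0.04, adjusted p 0.936), SESN2 (-0.07, adjusted p 0.877) and CHAC1 (1.32, adjusted p 0.104) did not pass, and nor did DELE1 (-0.30), EIF2AK1 (-0.11) or OMA1 (-0.08). An LSM14A copy (ENSG00000262860), uncertain because of its second copy, went from 0 reads to 58.9 ± 17.3, at least 16.8-fold higher against a floor of 3 reads per library.

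By limma 286 genes passed in DELE1 knockdown cells, 119 higher and 167 lower, with 2288 at unadjusted p under 0.05. The balance of rises and falls depended on scaling. With equal library totals 600 passed, 523 higher and 77 lower, and the median of all genes moved by 0.158 on the log2 scale, and with quantile normalization 184 passed, 105 higher and 79 lower. With no filter 176 passed. The count was 1208, 500 and 45 without untreated replicates 1, 2 and 3, 49, 80 and 65 without oligomycin replicates 1, 2 and 3, 459 without HRI knockdown untreated replicate 2 and 102 without both libraries that stand apart, 86 of them shared. Fitting only the 2 groups left 2 calls, the LSM14A copy and ZDBF2, and put MT-CO3 at adjusted p 0.115 and JUN at 0.232. Quantile normalization ended the calls of MT-ATP6 (log2 change 0.00, adjusted p 1), MT-CO1 (0.246), MT-ND1 (0.208) and MT-ND3 (0.0562), but it fixes the values of the highest ranks, where 11 of the 13 mRNAs lie.

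The other 13 genes picked by the naming rule in DELE1 knockdown cells did not hold in every fit that left out 1 library. They were the rises of RPLP0P2 (1.72), CSTB (1.39), DEPDC1B (1.37), SEC24A (1.28), ABCB10 (1.28), the second HSPA1B copy (1.19), ATXN2L (1.12) and RNF146 (1.11), and the falls of ZDBF2, MFSD12 (-1.18), SUPT4H1 (-1.09), SFXN4 (-1.08) and NUDT16L1 (-1.06). ZDBF2 went from 90.6 ± 26.9 to 0 reads, at least 29.1-fold lower against 3 reads per library. Without untreated replicate 3, adjusted p was 0.195 for RPLP0P2, 0.142 for CSTB, 0.216 for DEPDC1B, 0.27 for SEC24A, 0.139 for ABCB10, 0.0968 for the HSPA1B copy, 0.0756 for ATXN2L, 0.171 for RNF146, 0.191 for ZDBF2, 0.256 for MFSD12, 0.225 for SUPT4H1 and 0.251 for SFXN4. NUDT16L1 was at 0.0792 without oligomycin replicate 3. The highest adjusted p among these genes was 0.0951 without untreated replicate 2 (SEC24A), 0.143 without oligomycin replicate 1 (SFXN4), 0.126 without replicate 2 (SEC24A) and 0.203 without replicate 3 (SUPT4H1).

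As lists in DELE1 knockdown cells, the mitochondrially encoded mRNAs had a median of -0.67 (13 of 13 lower adjusted over the list alone; camera adjusted p 1.11e-25, 0.00667 with an estimated correlation), and the median was -0.22 after quantile normalization. ISR regulators rose in 2 of 15 (4 adjusted over the list alone; median 0.17; adjusted p 0.131), and passed by fry at 0.0106 and without the libraries that stand apart at 0.0149. Amino acid synthesis genes had 0 of 15 called (4 rose and 1 fell adjusted over the list alone; 0.213) and also passed by fry at 0.0106. The ER unfolded protein response fell in 4 of 21 (1 rose and 6 fell adjusted over the list alone; median -0.21; 0.0118, 0.118 with an estimated correlation), HSPA5 going from 1185 to 741. Glycolysis fell in 2 of 16 (6 adjusted over the list alone; median -0.19; 0.0154, 0.0686 with an estimated correlation). Cell cycle genes fell in 2 of 36 (2 rose and 9 fell adjusted over the list alone; -0.11, turning to 0.049 with equal library totals; 0.0259, 0.0686 with an estimated correlation) and histones in 2 of 14 (5 adjusted over the list alone; -0.15; 0.0326, 0.226 with an estimated correlation). Ribosomal protein genes fell in 8 of 76 (4 rose and 20 fell adjusted over the list alone; -0.08; 0.000986, 0.226 with an estimated correlation), and the sign turned with both scalings. Heat shock genes (1 rose and 1 fell of 12; 0.713), transporters (1 of 10 rose; 0.91), tRNA synthetases (1 of 19 fell; 0.0517), cholesterol synthesis (1 rose and 1 fell of 22; 0.122), mitochondrial chaperones (0.328), OXPHOS subunits (0.713), mitochondrial ribosome (0.0517) and immediate early genes (0.163) did not pass by camera, and nor did p53 (0.91), NRF2 (0.537) and hypoxia genes (0.91). By fry, cholesterol synthesis (0.0207) and immediate early genes (0.00954) passed, both higher. Without the libraries that stand apart, immediate early genes (0.0437) and the mitochondrial ribosome (0.000164) passed by camera. Heat shock genes had a median below 0 and a mean above it (0.05), and OXPHOS subunits a median and mean above 0 and a test pointing down.

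In HRI knockdown cells oligomycin asked what remains without the kinase. JUN rose from 341 ± 16.5 to 673 ± 5.69 (log2 change 0.98, adjusted p 2.99e-08) and HSPA1B from 129 ± 11.6 to 271 ± 24.2 (1.07, adjusted p 0.000143). MT-CO3 fell from 9887 ± 728 to 5395 ± 434 (-0.87, adjusted p 1.12e-06), beside MT-CO1 (-0.75), MT-CO2 (-0.79), MT-ND2 (-0.69), MT-ND4L (-0.52) and MT-ND1 (-0.46). Reads assigned to MTRNR2L12, a nuclear relative of mitochondrial ribosomal RNA, fell by 0.50 in log2 (adjusted p 0.00241). Quantile normalization turned this to 0.05 (adjusted p 0.853). SERF1B went from 1.08 to 78.8 (adjusted p 0.00207), uncertain because the value summed over its copies did not pass (0.901). ASNS (0.27, adjusted p 0.838), SESN2 (0.21, adjusted p 0.876), CHAC1 (0.56, adjusted p 0.869) and the 3 targets did not pass.

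By limma 14 genes passed in HRI knockdown cells, 4 higher and 10 lower, with 782 at unadjusted p under 0.05, while DESeq2 called 27. The share of calls that were higher was 28.6%, against 42.9% with equal library totals and 40% with quantile normalization. The count was 25 without DELE1 knockdown untreated replicate 3 and 28 without both libraries that stand apart. Fitting only the 2 groups ended the calls of MT-CO1 (0.0614), MT-ND1 (0.0822), MT-ND2 (0.136), MT-ND4L (0.0619) and MTRNR2L12 (0.192). The second HSPA1B copy, HIST1H1D and HIST2H2AC also passed, but each lost the threshold without at least 1 library. In the order HSPA1B copy, HIST1H1D and HIST2H2AC, adjusted p was 0.127, 0.127 and 0.0978 without HRI knockdown untreated replicate 1, and 0.184, 0.0832 and 0.0832 without untreated replicate 2. It was 0.181, 0.175 and 0.0615 without oligomycin replicate 2, and 0.183, 0.187 and 0.064 without oligomycin replicate 3. HIST1H1D was also at 0.238 without untreated replicate 3 and at 0.195 without oligomycin replicate 1.

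Mitochondrially encoded mRNAs fell in 6 of 13 cases in HRI knockdown cells (12 adjusted over the list alone; median -0.61; camera adjusted p 8.83e-35, 0.00144 with an estimated correlation). Replication histones fell in 2 of 14 (3 adjusted over the list alone; median -0.36; 4.6e-06), immediate early genes rose in 1 of 6 (1 adjusted over the list alone; median 0.13; 0.00519), and cell cycle (-0.12; 0.00151) and glycolysis genes (-0.16; 0.00496) were lower with 0 members called over all genes and 0 and 1 adjusted over the list alone. These held with an estimated correlation. Ribosomal proteins had a median of 0.07 (0.00202, 0.302 with an estimated correlation), which was 0.15 with equal library totals. For the ER unfolded protein response the test (0.000591) and median (-0.08, but 0.006 with equal library totals) pointed down and the mean (0.06) up, with 4 members lower adjusted over the list alone. ISR regulators (median 0.20; 0.0612) and amino acid synthesis genes (0.09; 0.157) did not pass by camera and passed by fry at 0.0209 and 0.0246. Transporters (-0.10; 0.157), tRNA synthetases (0.686), mitochondrial chaperones (0.0647), cholesterol synthesis (0.686) and heat shock genes (0.06; 0.341) did not pass, though heat shock did after quantile normalization at 0.00496 and without the libraries that stand apart at 0.0232, and mitochondrial chaperones did by fry at 0.0145 and without those libraries at 0.0442. OXPHOS subunits (0.174, 0.0236 after quantile normalization), the mitochondrial ribosome (0.204, 0.0232 without the libraries that stand apart), p53 targets (0.174), NRF2 targets (0.869) and hypoxia genes (0.962) did not pass.

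In OMA1 knockdown cells the question was what remains without the protease. ASNS rose from 96.2 ± 7.50 to 216 ± 38.9 (log2 change 1.14, adjusted p 0.0217) and TSC22D3, a glucocorticoid-induced leucine zipper gene, from 281 ± 7.24 to 457 ± 64.4 (0.69, adjusted p 0.0217). Other ISR genes did not pass one by one, with 138 ± 29.1 and 239 ± 21.1 for SESN2 (adjusted p 0.248) and log2 changes of 0.61 for STC2 and for PSAT1, 0.85 for SLC7A11 and 1.20 for CHAC1. As groups they were higher, with a median of 0.59 for ISR regulators (0 of 15 called, 3 adjusted over the list alone; camera adjusted p 6.27e-10, 3.27e-05 with an estimated correlation) and 0.39 for amino acid synthesis (1 of 15 called, 4 adjusted over the list alone; 5.48e-12, 1.45e-05 with an estimated correlation). Transporters (0.20; 2 adjusted over the list alone; 0.000814, 0.0444 with an estimated correlation) and tRNA synthetases (0.17; 2 adjusted over the list alone; 5.98e-05, 0.0433 with an estimated correlation) were also higher. Heat shock genes were lower (-0.24; 5 adjusted over the list alone; 2.04e-07, 0.000901 with an estimated correlation), HSPA8 standing at 2152 ± 138 and 1659 ± 124 (adjusted p 0.139). DELE1, EIF2AK1 and OMA1 did not pass.

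Those were the 2 genes that limma called in OMA1 knockdown cells, both higher, with 615 at unadjusted p under 0.05, 3 called by edgeR and 11 by DESeq2. The count was 1, neither of these genes, without OMA1 knockdown untreated replicate 1, 0 without untreated replicate 2 or 3 or oligomycin replicate 1 or 3, 10 without DELE1 knockdown untreated replicate 3 and 13 without both libraries that stand apart. ASNS and TSC22D3 were both at adjusted p 0.117, 0.159 and 0.0706 without untreated replicates 1, 2 and 3 and at 0.395 without oligomycin replicate 1, and at 0.112 and 0.0829 without oligomycin replicate 3. A filter at 50, equal totals and quantile normalization each gave 4 calls, the last with 75% higher, and the 2 groups alone gave 7, without TSC22D3 (0.0974). Mitochondrially encoded mRNAs had a median of -0.20 (2.11e-07, 0.0874 with an estimated correlation; -0.04 after quantile normalization) and ribosomal proteins 0.10 (6.27e-10, 0.0549 with an estimated correlation). For the ER unfolded protein response the test (0.00495, 0.0708 with an estimated correlation) and median (-0.10) pointed down and the mean (0.04) up. The other 11 lists did not pass, from 0.0674 for the mitochondrial ribosome to 0.983 for glycolysis, though without the libraries that stand apart the mitochondrial ribosome (0.0222) and cholesterol synthesis (0.0479) did.

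Whether the knockdown lines respond differently from control cells was tested directly as a difference of log2 responses. In DELE1 knockdown cells the response of SESN2 was lower by 2.17 on the log2 scale than in control cells (difference -2.17, SE 0.26, adjusted p 0.000133), that of SLC1A4 by 2.54 (difference -2.54, adjusted p 0.0108) and that of ASNS by 1.68 (difference -1.68, adjusted p 0.00209). The response of HSPA1B was higher by 2.86 (SE 0.19, adjusted p 4.46e-09) and that of HSPA8 by 0.82 (adjusted p 0.000479). In HRI knockdown cells the differences were -1.89 for SESN2 (adjusted p 0.000612), -2.97 for SLC1A4 (0.00235), -1.45 for ASNS (0.00581), 3.13 for HSPA1B (7.44e-10) and 0.95 for HSPA8 (9.74e-05). In OMA1 knockdown cells only HSPA1B (1.57, SE 0.19, adjusted p 0.000303) and HSPA8 (0.78, SE 0.11, adjusted p 0.00361) passed, while SESN2 (-1.29, adjusted p 0.0974), ASNS (-0.58, adjusted p 0.61) and CHAC1 (-2.16, adjusted p 0.265) did not. The targets did not pass in any difference.

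The naming rule also picked the second HSPA1B copy in DELE1 (3.04) and HRI knockdown cells (3.11), and CARS copy ENSG00000278191 (-4.97), DDR2 (-3.01) and CTH (-2.02) in HRI knockdown cells. CTH was at adjusted p 0.0513 without control oligomycin replicate 1 and 0.052 without HRI knockdown oligomycin replicate 1. SERF1B (7.58) did not pass when its copies were summed (0.876). CHAC1 (-2.80, adjusted p 0.0435) did not pass without the libraries that stand apart (0.0511) or without control untreated replicates 2 (0.112) and 3 (0.128), control oligomycin replicates 2 (0.125) and 3 (0.129), HRI knockdown untreated replicates 1 (0.0707), 2 (0.0934) and 3 (0.0756), or HRI knockdown oligomycin replicates 1 (0.0587), 2 (0.12) and 3 (0.0889).

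In DELE1 knockdown cells the rule picked CSTB (2.08), DDR2 (-2.43), SLC43A1 (-2.02) and the LSM14A copy (7.30). CSTB was at adjusted p 0.0517, 0.0545 and 0.0637 without control untreated replicates 1 and 3 and oligomycin replicate 3. DDR2 was at 0.0608 and 0.0521 without control untreated replicates 1 and 2, at 0.0645, 0.0556 and 0.0558 without control oligomycin replicates 1, 2 and 3, and at 0.054 and 0.0581 without DELE1 knockdown oligomycin replicates 1 and 3. SLC43A1 was at 0.0517 and 0.0633 without control untreated replicates 1 and 2, at 0.0533 and 0.0743 without control oligomycin replicates 2 and 3, and at 0.0699 and 0.0533 without DELE1 knockdown oligomycin replicates 1 and 2. The LSM14A copy was at 0.0637, 0.0683 and 0.0624 without control untreated replicates 1 and 3 and oligomycin replicate 1, and at 0.054, 0.0628 and 0.0575 without DELE1 knockdown oligomycin replicates 1, 2 and 3.

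As groups, the ISR regulators responded less than in control cells by a median of -0.78 in DELE1, -1.18 in HRI and -0.75 in OMA1 knockdown cells, with 4, 5 and 0 of 15 members lower (9, 10 and 8 adjusted over the list alone) and camera adjusted p of 9.76e-10, 2.25e-14 and 6.35e-09. Without the libraries that stand apart these medians were -1.15, -1.71 and -0.75. Amino acid synthesis differed by -0.72, -0.77 and -0.53, with 6, 6 and 0 members lower (10, 10 and 7 adjusted over the list alone; 8.89e-11, 5.74e-16 and 1.31e-08). Transporters differed by -0.86, -1.03 and -0.66, with 5, 5 and 0 of 10 lower (8, 8 and 7 adjusted over the list alone; 8.89e-11, 6.25e-17 and 3.05e-10). Heat shock genes lay above control by 0.71, 0.81 and 0.62, with 5, 7 and 2 of 12 higher (10, 11 and 10 adjusted over the list alone; 7.27e-17, 4.01e-26 and 8.65e-19), and cholesterol genes by 0.79, 0.54 and 0.40, with 6, 4 and 0 of 22 higher (11 higher and 1 lower, then 6 and 5 higher, adjusted over the list alone; 7.89e-09, 1.14e-08 and 8.41e-07). Every one of these calls held with an estimated correlation. The tRNA synthetases differed by -0.51 (6.23e-08), -0.33 (1.53e-06) and -0.14 (0.0447, 0.246 with an estimated correlation), with 2, 1 and 0 of 19 lower (11 lower, then 1 higher and 7 lower, then 1 lower, adjusted over the list alone).

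Mitochondrially encoded mRNAs fell more than in control cells by a median of -0.67 in DELE1 knockdown cells (8 of 13 lower, 12 adjusted over the list alone; adjusted p 7.27e-17, 0.00607 with an estimated correlation) and -0.56 in HRI knockdown cells (4 lower, 10 adjusted over the list alone; 1.69e-15, 0.0095 with an estimated correlation), and not in OMA1 knockdown cells (-0.07; 0.0545, 0.0171 without the libraries that stand apart). The DELE1 median was -0.17 after quantile normalization, which ended the calls of MT-CO3 in both lines (adjusted p 0.215 in DELE1 and 0.105 in HRI knockdown cells). Histones differed by -0.67 in DELE1 (2 lower, 4 adjusted over the list alone; 0.00249, 0.0965 with an estimated correlation) and -0.71 in HRI knockdown cells (1 lower, 2 adjusted over the list alone; 1.38e-06, 0.0114 with an estimated correlation). Ribosomal proteins differed by -0.20 in DELE1 knockdown cells (5 of 76 lower, 21 adjusted over the list alone; 7.89e-09, 0.0634 with an estimated correlation), and by -0.04 with equal library totals and -0.08 after quantile normalization. The ER unfolded protein response differed by -0.14 (0.02 with equal library totals), -0.16 and -0.16 (0.0122, 0.00993 and 0.0447; 0.0959, 0.0818 and 0.202 with an estimated correlation), and its mean was above 0 in HRI (0.06) and OMA1 knockdown cells (0.04). Mitochondrial chaperones (0.12; 0.0282, 0.0388 with an estimated correlation, 0.0519 after quantile normalization) and glycolysis (0.22; 0.00702, 0.0271 with an estimated correlation) lay above control in OMA1 knockdown cells. Lists not given here did not pass in a difference, except OXPHOS subunits in DELE1 knockdown cells without the libraries that stand apart (0.0373) and ribosomal proteins in OMA1 knockdown cells after quantile normalization (0.0173).

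By limma 134 genes differed in DELE1 (53 higher and 81 lower), 64 in HRI (25 and 39) and 2 in OMA1 knockdown cells (both higher), with 1750, 1004 and 856 at unadjusted p under 0.05. With equal library totals 72.3% of DELE1 calls were higher in place of 39.6%, the median of all genes moving by 0.152, and 59% of HRI calls in place of 39.1%. The DELE1 count was 56, 79 and 69 without control untreated replicates 1, 2 and 3, 69, 59 and 56 without control oligomycin replicates 1, 2 and 3, 433 without DELE1 knockdown untreated replicate 1, and 54, 72 and 65 without its oligomycin replicates 1, 2 and 3; the 4 groups alone gave 23. The HRI count was 148 without DELE1 knockdown untreated replicate 3 and 140 without both libraries that stand apart. The OMA1 count was 5 and 64 without DELE1 knockdown untreated replicates 1 and 3, 96 without both libraries that stand apart, 36 by DESeq2, 36 with the 4 groups alone, 15 with equal totals and 5 with quantile normalization, 80% of them higher.

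Genes called in both the DELE1 and the HRI difference numbered 44, with 16 higher (0.12 for independent lists) and 28 lower (0.29). All comparisons share the control libraries, which alone gave 0 shared calls in 50 simulations of unchanged groups but a covariance across genes of 0.169, against 0.285 observed, and a correlation of 0.497, against 0.557 observed, where genes are not independent replicates. The correlation of the OMA1 difference was 0.486 with the DELE1 difference (0.499 simulated) and 0.581 with the HRI difference (0.493 simulated). Without the libraries that stand apart 81 genes were shared. Both genes called in the OMA1 difference, HSPA1B and HSPA8, were called in the other two. Part of the observed overlap can come from the shared controls, since 3 control libraries cannot be divided between the comparisons.

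Whether the 3 knockdowns differ among themselves was tested with limma's F test. HSPA1B differed (adjusted p 0.000536), with log2 responses of 0.80 in DELE1, 1.07 in HRI and -0.50 in OMA1 knockdown cells. MT-CO3 differed (0.00545), at -0.95, -0.87 and -0.20, and JUN (0.029), at 0.64, 0.98 and 0.37. DDX24, an RNA helicase gene (0.029), responded by -0.96, -0.36 and 0.48. Copies of SERF1B (0.00545) and RPS18 (ENSG00000235650; 0.029) also passed and are uncertain. These 6 genes were all that limma called, of 1073 at unadjusted p under 0.05; DESeq2 called 41, 2 passed with values summed per symbol, and 17 passed without both libraries that stand apart. The count was 45 and 12 without DELE1 knockdown untreated replicates 1 and 3, 3 without DELE1 knockdown oligomycin replicate 1 or 2, 2 without HRI knockdown oligomycin replicate 2, and 3 without OMA1 knockdown untreated replicate 1, 2 or 3. DDX24, JUN and the copies lay outside the naming rule and were chosen after their values were seen.

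The mean over 59 preset ISR genes gave 1 number per line for the size of the response. It rose with oligomycin from 6.54 ± 0.017 to 7.48 ± 0.035 in control cells, a change of 0.94 on the log2 scale. The change was 0.08 in DELE1 knockdown cells (7.98% of the control change), 0.06 in HRI knockdown cells (6.81%) and 0.39 in OMA1 knockdown cells (41%). Exact permutation p was 0.1 in control and OMA1 and 0.2 in DELE1 and HRI knockdown cells, and 0.1 is the smallest that 3 against 3 libraries can give. The differences from control were -0.87, -0.88 and -0.56, with exact permutation p of 0.1, 0.1 and 0.09, adjusted to 0.12 over 6 comparisons, none past the threshold. The 400 arrangements allow 0.005, but untreated scores were close in all lines (means 6.44 to 6.54), so exchanging untreated libraries moved the difference little and p stayed near 0.1, the floor for 3 against 3 treated libraries. These p-values therefore decide little. The treated libraries lay at 7.455 or above in control cells and at 6.94 or below in the knockdown lines. DELE1 and HRI knockdown cells differed by -0.01 (exact permutation p 0.825). With equal library totals the DELE1 change was 0.232 and the HRI change 0.145, and after quantile normalization the HRI change was 0.038.

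**Figure D4:**
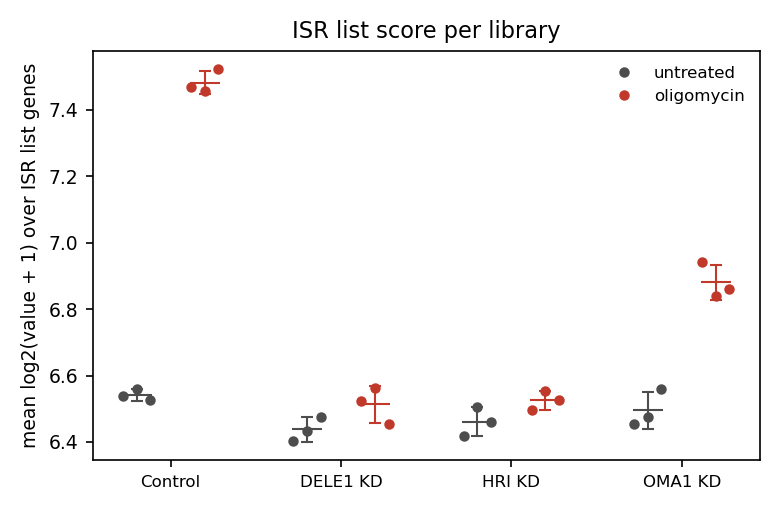
Mean log2(value + 1) over 59 ISR genes (y axis, not from 0) in each library of the 4 lines (x axis), with points for libraries, bars for mean and SD, grey for untreated and red for oligomycin. The treated control libraries lie near 7.48 and the treated OMA1 knockdown libraries near 6.88, while treated and untreated DELE1 and HRI knockdown libraries lie between 6.40 and 6.56.

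Doxycycline in wild-type cells asked whether another mitochondrial stress, loss of mitochondrial translation, changes the same genes. CHAC1 rose from 2.81 ± 0.371 to 59.8 ± 6.22 (log2 change 3.995, adjusted p 0.0123), SESN2 from 313 ± 94.5 to 1078 ± 103 (1.81, adjusted p 0.0269), STC2 from 148 ± 12.0 to 513 ± 127 and DDIT4 from 98.1 ± 12.7 to 450 ± 163. Amino acid genes rose as well, with CTH going from 52.8 to 189, PSAT1 from 353 to 1041, and MTHFD2, a mitochondrial folate enzyme, from 581 to 1029. HSPA1B fell from 1580 ± 341 to 467 ± 93.3 (-1.75, adjusted p 0.0238) and ID3, an inhibitor of helix-loop-helix factors, from 358 to 155. HSPA8 went from 4948 to 2982 and did not pass (adjusted p 0.0652), and nor did DELE1 (0.15), EIF2AK1 (0.18) or OMA1 (-0.11).

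Several of the largest changes were all or none. They are uncertain, since a move of reads to entries under other symbols was not tested. SDF4 (chromosome 1, 1216908 to 1232031) went from 0 reads to 667 ± 68.1, at least 158-fold higher against 3 reads per library, EIF3CL from 0 to 387 ± 7.44 (at least 91.8-fold), FUBP3 from 0 to 254 ± 3.39 (at least 60.3-fold), ERCC3 from 0 to 234 ± 3.83 (at least 55.6-fold), MSH6 from 0 to 324 ± 299 (at least 76.9-fold) and NTHL1 from 0 to 98.6 ± 11.7 (at least 23.4-fold). In the other direction, HLA-C copy ENSG00000233841 went from 172 to 0 (at least 80-fold lower), PRR3 copy ENSG00000206491 from 83.6 to 0 (at least 38.8-fold lower), APLP2 from 164 ± 73.9 to 1.04 and TAF15 from 96.0 to 0.327. TAF15 turned to a rise of 0.31 when values were summed per symbol, so its fall is uncertain. A filter at 50 ended the calls of MSH6, FUBP3, ERCC3, APLP2, NTHL1, TAF15 and CHAC1 and of the HLA-C, PRR3 and SERF1B copies (adjusted p 0.0958 to 0.517).

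By limma 26 genes passed with doxycycline, 20 higher and 6 lower, with 795 at unadjusted p under 0.05. A filter at 50 gave 11, DESeq2 42 and quantile normalization 12, with 58.3% higher in place of 76.9%. Each fit without 1 library left 1 in a group. CHAC1 and NTHL1 lost the threshold without treated replicate 1 or 2. Without untreated library 1, STC2, PSAT1, DDIT4, ID3 and the PRR3 copy did. Without untreated library 2, PSAT1, CTH, DDIT4, TAF15 and the PRR3 copy did, and CTH did without treated replicate 2. MTHFD2, SLC7A11 and GPT2 also lost the threshold without at least 1 library. A SERF1B copy (ENSG00000278839), which rose by 3.26, lost it without treated replicate 1 or 2. Quantile normalization put SESN2, STC2, PSAT1, CTH and HSPA1B at adjusted p 0.0522.

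Among lists with doxycycline, 4 of 16 ISR regulators rose (12 adjusted over the list alone; median 0.93; camera adjusted p 6.32e-16), 5 of 14 amino acid synthesis genes (14 adjusted over the list alone; 0.78; 7.09e-20) and 1 of 10 transporters (10 adjusted over the list alone; 0.86; 8.6e-15). The tRNA synthetases were higher (7 of 19 adjusted over the list alone; 0.35; 2.34e-05). Heat shock genes were lower (1 of 12 called, 6 adjusted over the list alone; -0.33; 3.79e-08), as were the mitochondrial (-0.18; 2.29e-07) and cytosolic ribosomal protein genes (-0.08; 0.000973). With an estimated correlation none of these passed (0.289 to 0.32), nor by fry (0.0826 to 0.189), and the remaining lists did not pass in any of these tests. The ISR score changed by 0.811, with an exact permutation p of 0.333, the smallest that 2 against 2 libraries can give.

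The responses to the drugs shared 10 rising genes among 9456 tested in both, where independent lists would share 0.34 (Fisher's exact p 1.93e-13). They were ASNS, CHAC1, CTH, DDIT4, GPT2, MTHFD2, PSAT1, SESN2, SLC7A11 and STC2. Among 6 genes that fell with doxycycline, HSPA1B was shared (0.12 for independent lists; Fisher's exact p 0.119). Of the genes called with oligomycin in control cells, 134 of 168 rises and 158 of 197 falls had the same sign with doxycycline.

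For markers of fibroblasts, neurons and hepatocytes, the highest group means in the knockdown set were 5.17 for COL1A1, 5.10 for MAP2, 3.07 for GAP43, 1.93 for STMN2, 1.79 for COL3A1, 1.75 for LUM, 1.52 for PDGFRA and 1.42 for APOA1. In the doxycycline set COL1A1 had a highest group mean of 9.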

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

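The tests of depth, of a swapped line, of library composition, of nuclear copies and of heat shock levels in treated cells, the splits that keep the treated libraries of a line together, and the fits without the 2 libraries that stand apart, were chosen only after the results were seen. The tests of composition and nuclear copies replaced earlier forms whose values had been seen. What singled out the results here was a test of the difference between the response of a knockdown line and the control response, or among the knockdown lines, except for the third pattern, where it was the position on the first principal component and the deviation from the group mean.

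The first pattern was that cytosolic heat shock genes fell with oligomycin in control cells and less or not in the knockdown lines. Their median differences from the control response were 0.714 in DELE1, 0.812 in HRI and 0.62 in OMA1 knockdown cells, with HSPA1B at 2.863, 3.133 and 1.568, its copy at 3.035 and 3.106 in DELE1 and HRI, and HSPA8 at 0.778 in OMA1 knockdown cells. Reads shared between HSPA1A and HSPA1B are argued against (lowest of the 3 medians 0.61 without these genes). So is scaling (lowest 0.574 over both scalings). The libraries that stand apart, absent from the OMA1 difference, are argued against for DELE1 and HRI, with medians of at least 0.62 without them. Untreated medians against control were -0.107 in HRI, where the call was lost with an estimated correlation (adjusted p 0.0638), -0.244 in OMA1 and 0.011 in DELE1 knockdown cells (-0.035 with equal totals), so a lower start may be part of the smaller fall in OMA1 and HRI knockdown cells. As the whole cause it is argued against, since treated knockdown cells stayed above treated control cells by medians of 0.675, 0.652 and 0.363 in DELE1, HRI and OMA1 knockdown cells, with a lowest median of 0.319 over both scalings. A candidate explanation is that the fall of these chaperone mRNAs depends on the relay that the knockdowns interrupt, but this is a hypothesis found on the same libraries. Oligomycin with an inhibitor of the ISR in control cells would test it, and no such library is among these. Other differences between the lines stay open as untested.

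The second pattern was that mitochondrially encoded mRNAs fell more with oligomycin in DELE1 and HRI knockdown cells than in control cells, by medians of -0.669 and -0.556. Composition and scaling as the whole cause are argued against by 3 scalings that leave the highest values free. In DELE1 and HRI knockdown cells the medians were -0.513 and -0.479 with equal totals, -0.632 and -0.575 with equal totals of the genes other than mitochondrially encoded and MTRNR2L genes, and -0.575 and -0.556 relative to the 50 nuclear genes nearest in mean value. Quantile normalization gave -0.168 and -0.442 but decides little here, since it fixes the values of the highest ranks and 11 of the 13 mRNAs had mean ranks of 3.1 to 24.2 among all genes. The libraries that stand apart are argued against for both lines, where the higher median without them was -0.468. Reads moving to the listed nuclear copies are argued against for both lines. Relative to control, the summed value of the 13 mRNAs changed by -60376 (SE 23224) in DELE1 and -29863 (SE 6186) in HRI knockdown cells, that of 17 nuclear copies of these mRNAs by -3381 (SE 1794) and -449 (SE 292), and that of 26 copies with the MTRNR2L genes by -87988 (SE 18815) and -74562 (SE 16498). The highest upper bound on a gain of the copies, at 2 SE and over both the deposited values and equal totals, was 0.93% of the loss. An effect of the knockdowns on mitochondrial RNA stays open as a hypothesis found on the same libraries and was not tested otherwise.

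The third pattern was that 2 untreated libraries, DELE1 replicate 3 and HRI replicate 2, stood apart from the rest. Low depth is argued against, since 3 other libraries had fewer reads than the shallower of them, and so is a swapped line, since at most 6.28% of the target's control level was left in them. Reads assigned to other copies of a gene are argued against, since the lower of their positions on the main axis was 33.5 with values summed per symbol, against at most 10.7 in the others. The design gives no biological explanation for a single library, and none was tested.

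The number of genes whose response differed from control was 134 in DELE1, 64 in HRI and 2 in OMA1 knockdown cells, and 6 differed among the knockdowns. In DELE1 knockdown cells the other single genes were an LSM14A copy at 7.299, SLC1A4 at -2.54, DDR2 at -2.43, SESN2 at -2.169, CSTB at 2.084 and SLC43A1 at -2.021. In HRI knockdown cells they were SERF1B at 7.577, a CARS copy at -4.967, DDR2 at -3.01, SLC1A4 at -2.969, CHAC1 at -2.803 and CTH at -2.023. The ISR regulators differed by medians of -0.783 in DELE1, -1.178 in HRI and -0.75 in OMA1 knockdown cells. Amino acid synthesis differed by -0.72, -0.765 and -0.529, transporters by -0.858, -1.032 and -0.664, tRNA synthetases by -0.507, -0.326 and -0.135, the ER unfolded protein response by -0.135, -0.161 and -0.155, and cholesterol synthesis by 0.788, 0.538 and 0.401, in the same order of lines. Ribosomal proteins differed by -0.195 in DELE1 knockdown cells (-0.04 with equal totals and -0.08 with quantile normalization), and histones by -0.668 in DELE1 and -0.707 in HRI knockdown cells. In OMA1 knockdown cells mitochondrial chaperones differed by 0.118 (adjusted p 0.0519 with quantile normalization) and glycolysis by 0.219. With an estimated correlation the ER unfolded protein response did not pass in any of the 3 lines (adjusted p 0.0959, 0.0818 and 0.202), nor did the tRNA synthetases in OMA1 knockdown cells (0.246), nor the ribosomal proteins (0.0634) and histones (0.0965) in DELE1 knockdown cells, and the median of the ER unfolded protein response in DELE1 knockdown cells turned to 0.02 with equal totals.

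Other splits of the same libraries were counted for each number of called genes. For the difference in DELE1 knockdown cells 1 of 100 splits, the real one with 134 genes, reached that number and the highest other gave 109. That share decides nothing, because splits that mixed the treated libraries of the lines gave at most 1 call. Of all 20 splits that kept the treated libraries of each line together, 2 reached 134 and the highest other gave 149, and 20 splits are too few for a share under 0.05. For the differences among the knockdowns 2 of 100 splits, the real one included, reached 6 and the highest other gave 9, and 0 of the others kept the treated libraries of each line together. Of 100 splits drawn to keep them together 50 reached 6 and the highest other gave 126. Such splits keep the differences between the treated lines, so these counts neither exclude chance nor point to it. It cannot be excluded for the HRI difference, where 8 of 100 splits reached 64 and the highest other gave 130, nor for the OMA1 difference, where 7 of 100 reached 2 and the highest other gave 48. Splits with several times the real count point to a structure of the samples, and all 7 other such splits for HRI and 5 of 6 for OMA1 kept the treated libraries of each line together. Of the 20 splits that kept them together, 16 reached 64 for HRI and 14 reached 2 for OMA1. With 10 splits the share cannot go below 0.05. Under that limit, the real count and the highest other were 378 and 0 for the control response (1 split as large), 286 and 0 for DELE1 (1), 14 and 1 for HRI (1) and 2 and 3 for OMA1 knockdown cells (2), and for untreated cells 4 and 2 in DELE1 (1), 3 and 0 in HRI (1) and 4 and 0 in OMA1 (1).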

How the results depend on the processing

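The fits without the 2 libraries that stand apart, the values summed per gene symbol and the doxycycline block were chosen only after the results were seen. The cause of the changes below was not tested. Fewer groups or libraries leave fewer residual degrees of freedom, but counts both rose and fell. Depth limits what could be seen, since a 2-fold change was recovered in 55.2% of simulated genes for a response, 31.3% for a difference between responses and 20.9% for doxycycline.

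With the 2 libraries that stand apart left out, 815 genes passed in the control response, 102 in DELE1, 28 in HRI and 13 in OMA1 knockdown cells, 140 in the HRI and 96 in the OMA1 difference, 6 in untreated HRI and 7 in untreated OMA1 knockdown cells, 17 among the knockdowns, and 81 genes were shared between the DELE1 and HRI differences. With only the groups compared, counts were 2 in the DELE1 and 7 in the OMA1 response, 23 in the DELE1 and 36 in the OMA1 difference, and 2, 7 and 8 in untreated DELE1, HRI and OMA1 knockdown cells. DESeq2 gave 27 in the HRI and 11 in the OMA1 response, 36 in the OMA1 difference, 37, 11 and 9 in untreated DELE1, HRI and OMA1 knockdown cells, 41 among the knockdowns and 42 with doxycycline. Equal library totals gave 600 in the DELE1 and 4 in the OMA1 response and 15 in the OMA1 difference. Quantile normalization gave 184 and 4 in the same responses, 5 in the OMA1 difference and 12 with doxycycline. With no filter 176 passed in the DELE1 response, and with the filter at 50 4 passed in the OMA1 response and 11 with doxycycline. Values summed per symbol gave 2 among the knockdowns. With an estimated correlation 44 list calls remained of 74, all 44 shared. The list tests that failed at the preset correlation and passed there once the libraries that stand apart were left out were mitochondrially encoded mRNAs (0.0384) and histones (0.0408) in the control response, ISR (0.0149), immediate early (0.0437) and mitochondrial ribosome genes (0.000164) in the DELE1 response, mitochondrial chaperones (0.0442), heat shock (0.0232) and mitochondrial ribosome genes (0.0232) in the HRI response, cholesterol synthesis (0.0479) and the mitochondrial ribosome (0.0222) in the OMA1 response, OXPHOS subunits in the DELE1 difference (0.0373), mitochondrially encoded mRNAs in the OMA1 difference (0.0171), ISR (0.0387), amino acid synthesis (0.00264) and ribosomal protein genes (0.000554) in untreated DELE1 and amino acid synthesis in untreated HRI knockdown cells (0.0026).

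The direction turned for 4 results of tests that passed at the deposited scaling or in the setting named. With quantile normalization the ribosomal proteins turned up in the DELE1 response (adjusted p 0.141; 1.2e-09 to 0.226 over all settings tried) and down in the OMA1 difference (adjusted p 0.0173; up to 0.9), and MTRNR2L12 in the HRI response went to 0.049 (adjusted p 0.853; from 1.13e-07 over all settings tried). With values summed per symbol TAF15 with doxycycline went to 0.306 (adjusted p 0.596; from 2.83e-05). List medians, without a test, turned in 31 of 190 cases, 29 with equal library totals and 10 with quantile normalization. Of these, 4 belonged to lists that had passed: ribosomal proteins in the DELE1 response (-0.084 to 0.078 and 0.066), and, with equal totals, cell cycle genes there (-0.111 to 0.049) and the ER unfolded protein response in the HRI response (-0.077 to 0.006) and the DELE1 difference (-0.135 to 0.02). Heat shock genes in the DELE1 response, which did not pass, turned from -0.062 to 0.1 and 0.117. The cause was not tested.

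Leaving out 1 library at a time gave 206 to 651 genes in the control response, 45 to 1208 in DELE1, 11 to 25 in HRI and 0 to 10 in OMA1 knockdown cells. The differences ranged from 54 to 433 in DELE1, 49 to 148 in HRI and 2 to 64 in OMA1 knockdown cells. Untreated counts ranged from 1 to 693, 3 to 8 and 2 to 6 in the same order, those among the knockdowns from 2 to 45, and those with doxycycline from 36 to 50, with 42 and 48 when untreated library 1 or 2 was left out. There the lone library left in a group is assumed to vary like the other group. The ISR score change ranged from 0.92 to 0.953 in control, 0.05 to 0.104 in DELE1, 0.042 to 0.086 in HRI and 0.355 to 0.416 in OMA1 knockdown cells. Of the named genes called, 16 of 20 in the control response, 7 of 20 in DELE1, 10 of 14 in HRI, 0 of 2 in OMA1 knockdown cells and 9 of 16 with doxycycline stayed called without any 1 library.

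Whether treated and untreated libraries of the same number were handled together is not stated, and a replicate block gave 341 genes in the control response, 214 in DELE1 and 14 in HRI knockdown cells, and 108 and 60 in the DELE1 and HRI differences. Over the 12 pairs of same-numbered treated and untreated libraries the correlation of residuals ran from -0.0575 to 0.0596, so 0 exceeded 0.1, and 9 of 24 libraries correlated best with their own number. For doxycycline the labels do not say which sample each untreated column holds, so its block used the number in the column names, with 1 residual degree of freedom. This replicate block gave 30 genes, 23 of them shared with the 26, and the correlation of residuals within a pair was 0.044. HSPA8 (adjusted p 0.0115) and HSP90AA1 (0.0227) passed there, and none of the 7 list calls changed.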

Other observations

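All values here were chosen after they were seen, and none was tested.

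Mitochondrially encoded mRNAs made up 6.57% ± 0.283 of the reads in untreated and 6.15% ± 0.136 in oligomycin-treated control cells (n = 3). In DELE1 knockdown cells the shares were 8.11% ± 1.82 and 4.81% ± 0.134, in HRI knockdown cells 6.14% ± 0.432 and 4.12% ± 0.215, and in OMA1 knockdown cells 7.26% ± 0.470 and 6.46% ± 0.145. The share was 10.2% in DELE1 knockdown untreated replicate 3, the highest of the 24 libraries. Genes of the MTRNR2L family, nuclear relatives of mitochondrial ribosomal RNA, took 11.2% and 12.6% of the reads in control cells without and with oligomycin, 11.5% and 8.91% in DELE1, 10.04% and 7.31% in HRI and 9.56% and 8.28% in OMA1 knockdown cells. In the doxycycline set they took 0.241% and 0.258%, and the mitochondrially encoded mRNAs 1.79% and 1.78%, without and with the drug.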
